A study of Caenorhabditis elegans with 2 samples.

How the data were processed

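Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA bound by a chosen protein. Here the protein was CEH-16, the engrailed-class homeodomain transcription factor of Caenorhabditis elegans, carried as an eGFP fusion by the strain OP82. Both samples came from whole L2 larvae of mixed sex, and the labels number them as biological replicates 1 and 2 of 1 group. There is no second group, stage or factor, so every comparison is within the peak lists or between the 2 replicates. The control library named in the labels was not analysed here.

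The authors deposited peak lists and no read counts. Per the file headers, each replicate has a relaxed list of peaks and background intervals. These were made as input for the irreproducible discovery rate (IDR), a method that compares peak ranks between lists. A pooled relaxed list and an optimal IDR-thresholded list were derived from the alignments or peak lists of both replicates. Of the 1358 IDR peaks, 1345 overlapped an interval of the replicate 1 list and 1350 one of the replicate 2 list. Each list was deposited for the builds ce10 and ce11. The signal of each interval, the enrichment value written by the authors' peak caller, was deposited on the scale of that caller. The deposited lists also hold the −log10 of a q-value per interval, and the summit position as an offset from the interval start. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Read depth is unknown, because no file gives counts, and the number of intervals does not measure it.

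The q-value column could not rank the IDR peaks, since all 1358 of them share 1 value, so peaks were ranked by signal. Intervals were mostly of a fixed width, with a median of 296 bp in the pooled and IDR lists, 310 bp in replicate 1 and 270 bp in replicate 2. The IDR list was not an exact subset of the pooled list: 861 of its peaks had identical coordinates there, and all 1358 overlapped a pooled interval by at least 1 bp. The relaxed lists have lengths of 28214 and 30000 intervals for replicates 1 and 2 and 30000 for the pooled data, so they hold many intervals of weak signal. The top peaks of a list are therefore the 1358 of highest signal, as many as there are IDR peaks.

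All positions are 1-based on ce11 (WBcel235) and were compared with the Ensembl release 115 annotation of that build. The ce10 files were used only to count peaks, to compare the replicates and to count peaks per chromosome, and no coordinate was converted. A summit was assigned to a promoter when it lay within 1000 bp of the annotated 5′ end of a protein-coding transcript, called the TSS here. Many worm transcripts are trans-spliced, so this end is often a splice acceptor or start codon and not the site of initiation. A gene had a peak when it owned the nearest such TSS within 1000 bp of a summit. Summits were further classed, in order, as promoter, coding exon, UTR, intron, noncoding gene or intergenic.

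Promoter and feature shares were compared with 1000 relocations of the peaks to random places on the same chromosomes outside the peaks. The promoter test was one-sided for a higher share and the feature test was two-sided. The promoter share was also compared with the 28562 pooled intervals that overlap no IDR peak, by Fisher's exact test. Overlap of the top peaks of the 2 replicates, by at least 1 bp, was tested against 1000 relocations, one-sided. Signal agreement used Pearson's r on log2 signal and Spearman's rho over IDR peaks that overlap an interval in both replicates, each with 100000 permutations. The 18 gene lists were compared with all 19973 protein-coding genes by two-sided Fisher's exact tests. They cover epidermal, developmental and housekeeping genes and markers of other tissues of the whole larva. The homeodomain core (TAATTA, TAATTG or CAATTA on either strand) was counted within 100 bp of each summit and compared with 100 shuffles that keep dinucleotide content, one-sided, and with windows centred 500 bp to each side by an exact McNemar test. All 2080 6-mers, with reverse complements merged, were compared between IDR windows and windows of the other pooled intervals by Fisher's exact test. Peaks per chromosome were compared with chromosome length by exact binomial tests. Median log2 signal at promoters and elsewhere was compared by a two-sided permutation test with 100000 permutations. P-values over feature classes, lists, 6-mers or chromosomes were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Intervals on shares are 95% Wilson intervals, and those on odds ratios are exact 95% intervals. Both cover counting error only and not the variation between animals or libraries, which 2 replicates cannot estimate well.

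The named genes follow a rule fixed, with the lists and tests, before the data were examined. It takes ceh-16, the genes of the 25 IDR peaks of highest signal that have a gene and overlap a top peak in both replicates, and every member with a peak of the lists for seam and epidermal regulators, fusogens and apical junctions, Wnt signalling, heterochronic genes, and Hox genes and cofactors. From each other list it takes up to 4 members of highest signal. It also takes eff-1, aff-1, lin-17, apr-1, egl-18, elt-6 and nhr-25 with or without a peak. Genes outside the rule are marked as chosen after their values were seen, apart from unc-119, which was taken from the strain description.

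Alternatives replaced the IDR list by the top peaks of either replicate, which leaves the other one out, by the top pooled intervals, or by the 679 IDR peaks in the upper part of the signal range. Others used windows of 500 and 2000 bp, peak midpoints, other overlap rules, other list backgrounds, a motif window of 50 bp, TAATTA alone, and the ce10 files. GC-matched backgrounds, the analyses of noncoding genes and of peaks found in 1 replicate alone, the split of lists by X linkage and the lists without ribosomal protein and histone genes were chosen after seeing the data. Sequence uniqueness was measured as the percent of 31-mers that occur once in the genome.

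The scripts were tested on simulated data. Of 20 randomly placed lists, 2 passed the promoter threshold, and a list with 30% of its peaks moved onto TSSs gave permutation p = 0.01, the smallest that run could give. Core sites planted in 200 windows of randomly placed peaks, not shuffled, gave permutation p = 0.0099. Shuffled windows without planted sites gave permutation p = 0.663, so these 2 runs differ in more than the planting. In the 6-mer test 0 of 2080 6-mers were called in shuffled sequence, and a planted 6-mer ranked first. Among 100 random target sets 4 had any list called. Ribosomal proteins were called in 100 of 100 sets with 20 planted members, and heterochronic genes in 48 of 100 sets with 4 planted members, so short lists have limited power. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.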

Results

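CEH-16 was mapped in L2 larvae through an eGFP fusion and ChIP-seq, in 2 biological replicates. The labels give the target, stage and strain and no further aim, so the questions below are where the tagged protein was recovered, at which genes, at which sequences, and how alike the replicates were. The IDR-thresholded list held 1358 peaks on ce11, with widths adding to 393 kb (overlaps not merged) and signal values from 23.2 to 190. The relaxed lists held 28214 intervals for replicate 1, 30000 for replicate 2 and 30000 for the pooled data. No counts were available, so the read depth behind a signal value is unknown. Each peak carries 1 pooled value and, where it overlaps an interval of a replicate, 1 value for that replicate.

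Among the strongest peaks were those beside rpl-3, fasn-1 and elt-1. The highest signal, 190, was at III:3867481-3867665, in intergenic sequence 283 bp upstream of rpl-3 (WBGene00004414), which encodes a large-subunit ribosomal protein. It was 84.9 in replicate 1 and 103.4 in replicate 2. Among the 10 highest peaks were also those of the ribosomal protein genes rpl-35 (signal 127.7, III:7854634-7854761, 444 bp upstream) and rpl-15 (signal 124.2, IV:654859-655000, 354 bp upstream). fasn-1, the fatty acid synthase gene, had the third highest signal (145.1) at I:8985956-8986185, in an intron 454 bp downstream of a TSS. elt-1 (WBGene00001249), a GATA factor that specifies epidermal fate, had a peak of signal 105.1 at IV:9615604-9615834, in an intron 277 bp upstream of a TSS, with 58.9 and 48.9 in replicates 1 and 2.

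These genes belong to the 25 highest peaks with a gene and support in both top lists, which were not tested for shared functions. Among the others were iff-2, an eIF5A gene (signal 113.9), eif-3.C (93.7) and drr-2, an eIF4H-like gene (89.7). cdc-48.1, which encodes a p97 ATPase, had a signal of 126.9, and hsp-3, which encodes an ER chaperone of the BiP class, had 92.5 with the summit 8 bp upstream of its TSS. cbp-1, a CBP/p300 acetyltransferase gene, had 118.1, the zinc finger gene tlp-1 had 108.4 and fzr-1, an activator of the anaphase-promoting complex, had 104.4. The epsin gene epn-1 (99.2) and the Gq alpha gene egl-30 (96.0) were also among the 25, as were the histone genes his-68 (92.2) and his-31 (88.2). The peak at egg-5 (93.6) lay within 200 bp of sls-2.4, an SL2 spliced leader RNA gene chosen after its value was seen, so its assignment to egg-5 is uncertain. The remaining members, given without a function here, were Y24D9A.6, Y17G9B.5, tag-340, serp-1.1, F48F7.5, eelo-2 and nspc-17, with signals from 91.2 to 144.6.

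Summits gathered upstream of protein-coding genes and, beyond 1000 bp of a TSS, were scarce in coding exons. Of the 1358 IDR summits, 755 (55.6%, interval 52.9 to 58.2%) lay within 1000 bp of a TSS, against a mean of 40.1% after relocation. The median promoter summit was 244 bp from its TSS, and 636 lay upstream against 117 downstream. Coding exons away from promoters held 13 summits (0.957%), against 13% after relocation, and 20 (1.47%) of the top peaks of replicate 1 alone. UTRs away from promoters held 0.589% against 2.14%, and introns away from promoters 14.7% against 20.2%. Promoter summits that also lay in a UTR or intron are not in these shares. Intergenic sequence beyond 1000 bp held 328 summits (24.2%), against 21.4% after relocation. Noncoding genes away from promoters held 4.05% against 3.17%.

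The promoter excess passed its one-sided permutation test with p = 0.000999, the smallest that 1000 relocations can give. Pooled intervals outside the IDR list were at promoters less often, at 46.2%, with an odds ratio of 1.46 (interval 1.31 to 1.63) and p = 1.18e-11 by Fisher's exact test. In a separate two-sided permutation test 5 of the 6 feature classes passed after adjustment, with p = 0.003 for promoters, coding exons, UTRs and introns and 0.0144 for intergenic sequence, while noncoding genes gave 0.0999 and passed with the top peaks of replicate 1 alone (4.57%, 0.0144). The intergenic call ended with the top peaks of replicate 2 alone, the top pooled intervals and the IDR peaks of higher signal, with adjusted p of 0.144, 0.12 and 0.316 and shares of 23.1%, 23.4% and 23.3%. Within 1000 bp of 31.1% of the promoter summits lay TSSs of 2 or more genes, so the gene named is the nearest and not the only one.

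**Figure D1:**
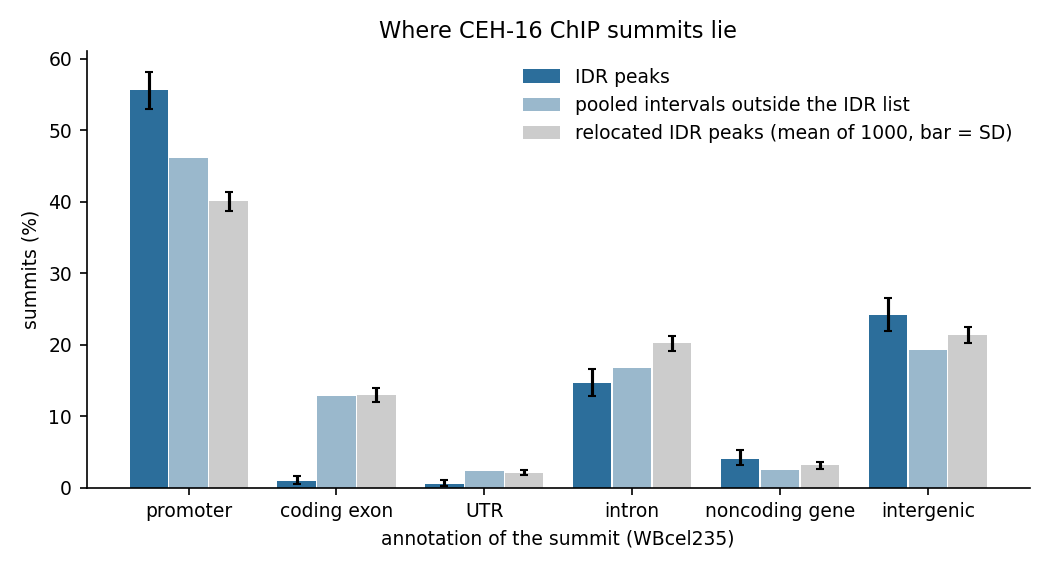
Percent of summits (y axis) in each annotation class (x axis) for the 1358 IDR peaks with 95% Wilson intervals, for the 28562 pooled intervals outside the IDR list, and for relocated IDR peaks as the mean and SD of 1000 relocations. Promoters hold 55.6% of IDR summits against 40.1% after relocation, and coding exons beyond 1000 bp of a TSS 0.957% against 13%. All classes other than promoter count only summits beyond 1000 bp of a TSS.

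No difference in signal between promoter peaks and other peaks was detected. The median signal was 33.5 at the 755 promoter peaks and 33.5 at the 603 others, a log2 difference of 0.00089 (two-sided permutation p = 0.977).

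Peaks lay at some of the genes that set epidermal fate and larval timing. No untagged library was analysed here, so recovery without the tagged protein was not excluded at these genes. Of 18 seam and epidermal regulators, 4 had a peak (22.2%, interval 9.0 to 45.2%), against 3.52% of all protein-coding genes. These were elt-1, the nuclear receptor genes nhr-23 and nhr-25, which act in molting and epidermal development, and sma-9, a zinc finger gene of the BMP pathway that regulates body size. nhr-23 had 3 peaks within 1000 bp of its TSSs, the strongest with signal 49.6 at I:7216125-7216420. nhr-25 (WBGene00003623) had 2, with signals 45 at X:13009730-13010025, in an intron, and 31.1. elt-1 had a second peak of signal 66.1, and its window held TAATTA at IV:9618992-9618997. sma-9 had signal 32.3, and TAATTA lay at X:10769647-10769652 within 100 bp of its summit. Of the 21 peak windows examined at 14 named genes, only these 2 held a core site, and 19 held none, among them those of the strongest elt-1 peak and of all nhr-23 and nhr-25 peaks.

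Heterochronic genes, which set the order of larval stages, carried peaks at 7 of 18 (38.9%, interval 20.3 to 61.4%). They were puf-9, a Pumilio-family gene (signal 77.0), lin-14, which specifies early larval fates (49.6), the nuclear receptor gene daf-12 (42.6), ain-1, a GW182-family gene (36.9), lin-66 (33.7), the RNA-binding protein gene lin-28 (28.2) and the Argonaute gene alg-1 (24.1). Of these, 3 had a top peak in only 1 replicate. ain-1 (30.7 and 3.2 in replicates 1 and 2) and lin-66 (25.3 and 10) had no top peak in replicate 2, and lin-28 (10.7 and 22.9) had none in replicate 1. The lin-14 peak was at X:11465217-11465512, in intergenic sequence 195 bp upstream of a TSS. The lin-28 peak was at I:8411133-8411428, also intergenic, 477 bp upstream.

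Hox genes and cofactors had peaks at 3 of 11 members. unc-62, a Meis-class cofactor gene, had 4 peaks, the strongest with signal 54.8 at V:4507747-4508042. The Hox genes ceh-13, of the labial class, and lin-39, which acts in the mid-body, had signals of 46.3 and 29.4. The lin-39 summit, 33 bp downstream of its TSS, lay in a UTR. Among 99 homeobox genes as a whole, 4 had a peak, these 3 and ceh-38 (35.2), an odds ratio of 1.16 (interval 0.308 to 3.07, Fisher's exact adjusted p = 0.936).

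In the IDR list, ribosomal protein genes gave more genes with a peak than any other gene list. With the top peaks of replicate 2 alone they tied with nuclear hormone receptors, at 21 genes each. Of 79 ribosomal protein genes, 28 had a peak (35.4%, interval 25.8 to 46.4%), led by rpl-3, rpl-35, rpl-15 and rpl-12 (signal 86.2). All 28 summits were upstream of the TSS, and they spanned signals from 24.2 to 190. Their median signal was 34.6 against 33.2 at other promoter peaks, a difference that did not pass (permutation p = 0.686, chosen after the data were seen). Core and linker histone genes had peaks at 11 of 58 (19%, interval 10.9 to 30.9%), led by his-68, his-31, his-60 (84.7) and his-4 (78.8). In the peak at his-42 only 14.7% of 31-mers occur once in the genome, and in those at his-5 and his-64 75.2% and 78.6%, so reads there may belong to other copies. These 3 genes were chosen after their values were seen. Nuclear hormone receptor genes had peaks at 20 of 274 (7.30%, interval 4.77 to 11%), led by nhr-137 (55.9), nhr-23, nhr-25 and daf-12. The leading receptor and ribosomal protein genes named here had a top peak in both replicates, but several other members did not. nhr-179 (3.5 and 15 in replicates 1 and 2) and nhr-91 (4.6 and 18) had one in replicate 2 alone, and rpl-6 and rps-4 in neither. These examples were chosen after their values were seen.

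These 6 lists passed two-sided Fisher's exact tests adjusted over the 18 lists. The odds ratios, with adjusted exact p, were 15.6 for ribosomal proteins (adjusted p = 7.42e-20), 17.6 for heterochronic genes (1.32e-05) and 6.50 for histones (2.87e-05). Those of the other 3 were 2.19 for nuclear hormone receptors (0.0105), 7.87 for seam and epidermal regulators (0.0113) and 10.3 for Hox genes and cofactors (0.0174). The first 3 passed under every alternative that counted all chromosomes together. With the top peaks of replicate 2 alone their odds ratios were 9.54 for ribosomal proteins, 9.94 for heterochronic genes and 4.15 for histones. Their widest values were 34.6 and 9.98 for ribosomal proteins and histones with every gene within 1000 bp, and 8.83 and 27.4 for heterochronic genes, with genes that have a pooled interval as background and with a 2000 bp window. Counting every gene within 1000 bp lets neighbouring genes share 1 summit, so those genes are not independent. The nuclear hormone receptor call ended with the top peaks of replicate 1 alone (odds ratio 1.49, adjusted exact p = 0.248), the IDR peaks of higher signal (1.44, 0.576), a 500 bp window (1.71, 0.15) and every gene within 1000 bp (1.68, 0.0679). With genes that have a pooled interval as background the odds ratios were 5.03 for seam and epidermal regulators and 7.53 for Hox genes and cofactors, each with adjusted exact p = 0.0513, and the Hox call also ended at a 500 bp window (odds ratio 7.60, 0.135) and among the IDR peaks of higher signal (12.2, 0.0576). In both of these 2 of the 11 genes had a peak, against 3 in the main setting. With the top peaks of replicate 1 alone the Hox odds ratio was 15.8.

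Other epidermal lists were not called. Fusogens and apical junctions had peaks at 2 of 16 members, dlg-1, a Discs large gene (41.9), and vab-10, a spectraplakin gene, with adjusted exact p = 0.214. Within 1000 bp of its TSSs vab-10 had 3 peaks, and a peak of signal 64.8 lay further away. The strongest of the 3 had signal 29.8 (5.7 and 17.4 in replicates 1 and 2) and overlapped no top peak of replicate 1. The list passed with a 2000 bp window (4 of 16, adjusted exact p = 0.0133). Its odds ratio was 3.92 in the main setting and 6.37 with the top peaks of replicate 1 alone. Wnt signalling had 3 of 31, the Dishevelled genes mig-5 (70.1) and dsh-2 (31.1) and the Nemo-like kinase gene lit-1 (25.1), with adjusted exact p = 0.212. Hedgehog-related and patched-related genes had 5 of 85 (adjusted exact p = 0.371). Neighbouring genes grd-13, grd-3 and grd-10 carried peaks of 55.3, 43.9 and 42.3 within IV:3438064-3441176, and wrt-10 had 31.8. Cuticle collagens had 7 of 176 (adjusted exact p = 0.873), led by dpy-3 (37.3), col-172 (36.4), col-107 (33.6) and col-10 (28.8). Their odds ratio was 1.14, and 1.85 with the top peaks of replicate 1 alone (11 of 176).

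The proteasome list, with pbs-1 (35.3), pas-5 (31.4), rpn-3 (26.3) and rpt-2 (24.8) among 33 genes, had an adjusted p of 0.0712. It passed with the top peaks of replicate 2 alone (0.00408) and with every gene within 1000 bp (0.0478). Heat shock proteins had 2 of 20, hsp-3 and hsp-1 (27.9), with adjusted exact p = 0.279, and 7 of 20 when every gene within 1000 bp was counted (adjusted p = 0.000106). Under that rule neighbouring genes can share 1 summit, so the genes counted are not independent. The heat shock odds ratio was 3.05 in the main setting and 4.87 with the top peaks of replicate 1 alone. Lists of markers of other tissues in the larva each had 0 or 1 genes with a peak, too few to exclude an enrichment. Peaks were at 0 of 27 intestine markers, 1 of 28 body wall muscle markers (pat-4, 30.3), 1 of 19 pharynx markers (peb-1, 73.4), 1 of 27 pan-neuronal genes (syd-2, 35.2) and 1 of 35 germline genes (nos-3, 25.8). The adjusted p was 0.741 for pharynx, 0.858 for neurons and 1 for the other 3. The upper limits were 12.5% for intestine, 14.5% for germline, 17.7% for muscle, 18.3% for neurons and 24.6% for pharynx. The pharynx odds ratio had an interval up to 9.68, which includes the 7.87 of the seam and epidermal list.

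**Figure D2:**
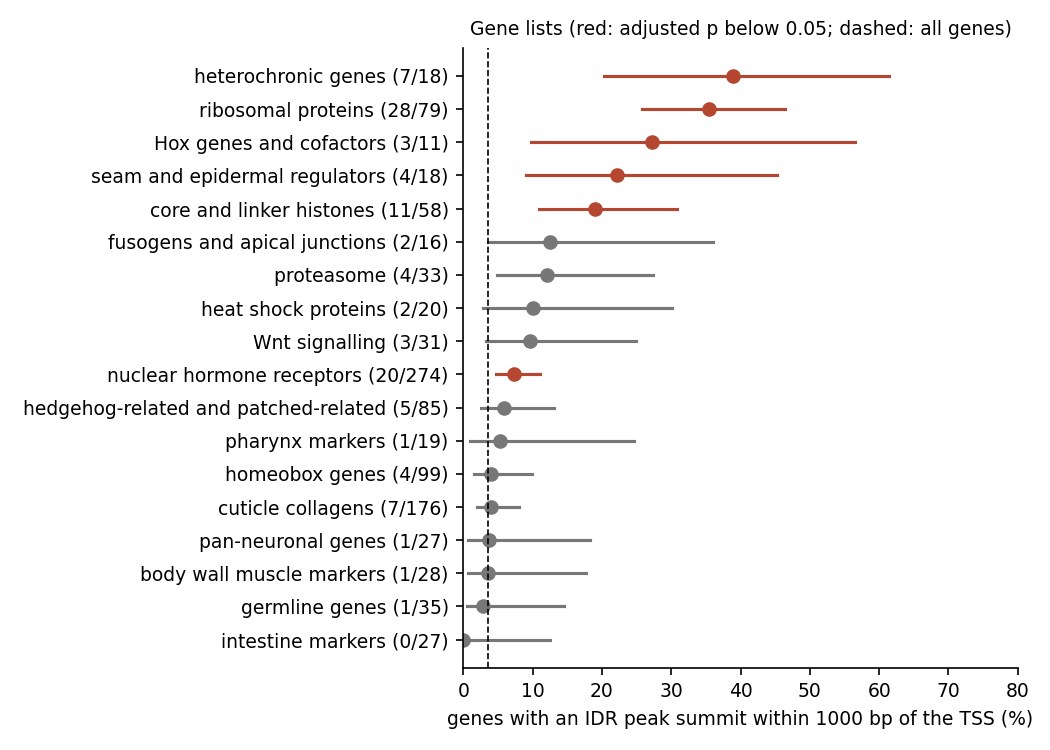
Percent of genes in each list with an IDR summit within 1000 bp of their TSS (x axis), as points with 95% Wilson intervals, and the number of genes with a peak over the list size. The dashed line marks all protein-coding genes at 3.52%, and the 6 lists in red had adjusted p below 0.05.

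Several genes linked to seam cell division and fusion had no IDR peak by the 1000 bp rule. For the fusogen genes eff-1 and aff-1 the nearest IDR summits were 7.68 and 25.1 kb from a TSS, and for the Wnt pathway genes lin-17 and apr-1 17.7 and 25.3 kb. The relaxed pooled list did hold intervals at eff-1 (signal 8.04, 25 bp from a TSS), apr-1 (8.37, 396 bp) and lin-17 (4.91, 314 bp), far below the IDR minimum of 23.2. egl-18 (WBGene00001186), a GATA factor gene of seam cells at IV:1902322-1917840, had its nearest IDR summit inside the gene, at IV:1911561 with signal 41. This summit lay 1885 bp from a TSS of egl-18 and was also the nearest to the neighbouring gene elt-6, at 6.42 kb. With a 2000 bp window 6 of 18 seam and epidermal regulators had a peak (odds ratio 10.9, adjusted exact p = 0.000378).

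The ceh-16 gene itself (WBGene00000439, III:8622735-8626314) had no IDR peak, and the nearest was 45 kb from its TSS. Neither relaxed replicate list, nor the pooled list, held any interval between III:8600941 and III:8630656, a stretch of 29.7 kb. It also covers rha-2, polk-1 and most of gpr-1, named after the stretch was seen, 8 protein-coding genes in all counting ceh-16. The first pooled interval past the right end, at III:8630879-8631174, had a signal of 26.8 and the lowest q-value of that list, yet is not an IDR peak.

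**Figure D3:**
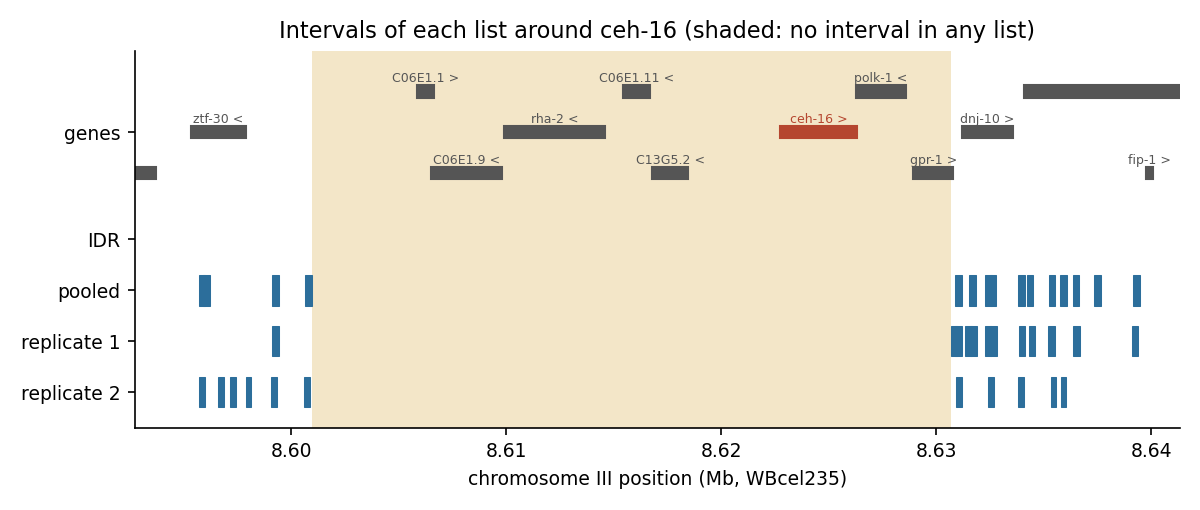
Map of chromosome III around ceh-16 (x axis, Mb on WBcel235) with the intervals of each list as blue boxes and protein-coding genes above, strand shown by arrows. The shaded 29.7 kb holds no interval of any of the 4 lists.

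The X chromosome held the most peaks for its length. It carried 346 IDR peaks (25.5%, interval 23.2 to 27.9%) on 17.7% of the genome, or 19.5 peaks per Mb. Chromosome V held 188 (13.8%) on 20.9% of the genome, 8.98 per Mb, and chromosome IV 179 (13.2%) on 17.4%. Chromosomes I, II and III held 226, 212 and 207. The exact binomial tests gave adjusted p = 4.06e-12 for the excess on X, 9.69e-11 for the deficit on V and 4.09e-05 for that on IV, and 0.138 to 0.706 for the other 3. Pooled intervals outside the IDR list were on X in 19.2% of cases. X-linked summits were at promoters in 51.2% of cases against 57.1% on autosomes (Fisher's exact p = 0.06).

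**Figure D4:**
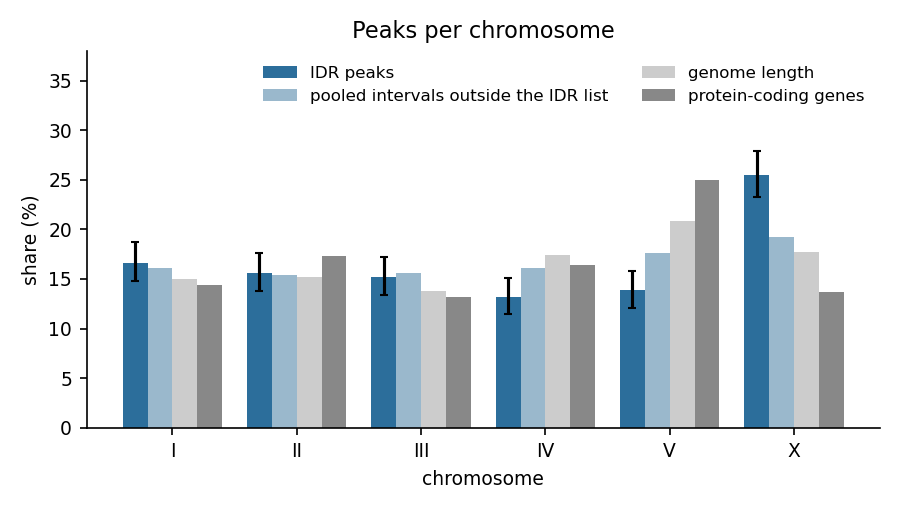
Share in percent (y axis) of IDR peaks with 95% Wilson intervals, of pooled intervals outside the IDR list, of genome length and of protein-coding genes on each chromosome (x axis). The X chromosome holds 25.5% of IDR peaks and 17.7% of the genome length.

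The homeodomain core was present in few summit windows. TAATTA, TAATTG or CAATTA lay within 100 bp of 209 of 1358 summits (15.4%, interval 13.6 to 17.4%), against a mean of 14.5% in shuffles of the same windows (one-sided permutation p = 0.109). Windows centred 500 bp to either side held it more often, in 23.4% and 22.8% (exact McNemar p = 1.39e-07 and 8.99e-07). Those flanks had a mean GC of 36.4% against 45.1% at the summits, and GC-matched intervals outside the IDR list, chosen after seeing the data, held the core in 13.5% (Fisher's exact p = 0.0859). TAATTA alone was in 6.41% of windows against 4.49% in shuffles, with permutation p = 0.0099, the smallest that 100 shuffles can give. The permutation test of all 3 sites also passed with a 50 bp window (7.07% against 5.91%, p = 0.0396), among the IDR peaks of higher signal (17.5% against 14.1%, p = 0.0099) and for the top peaks of replicate 2 (17.8% against 15.4%, p = 0.0297), and not for those of replicate 1 (14.8% against 14.1%, p = 0.257).

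Against the other pooled intervals GAGAGA had the lowest p of the 6-mers. It was within 100 bp of 40.8% of IDR summits and 16.7% of the other pooled summits (odds ratio 3.43, adjusted exact p = 8.66e-89). AGAGAG (35.4% against 13.6%), AGAGAC (30.1% against 10.7%), CGTCTC (27.8% against 9.54%) and GCGCAC (16.3% against 4.3%) followed. In the same 21 windows, chosen after their values were seen, GAGAGA or its complement lay in 11. These included the strongest peaks at rpl-3, elt-1, his-68, puf-9 and unc-62, but not those at mig-5, lin-14, lin-39 and lin-28. The 31 bp at the rpl-3 summit, III:3867556-3867586, read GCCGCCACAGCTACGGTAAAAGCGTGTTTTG, and those at the elt-1 summit, IV:9615698-9615728, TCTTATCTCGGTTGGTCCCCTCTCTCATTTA. AT-rich words such as CTGAAA (11.6% against 31.0%) and AAAATT (32.2% against 54.7%) were less frequent at IDR summits.

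By Fisher's exact test with adjustment over 2080 6-mers, 731 were more frequent at IDR summits and 526 less frequent. The windows differed in base composition, with a mean GC of 45.1% at IDR summits and 38.3% at the others. Against 4074 GC-matched intervals, the number of more frequent 6-mers was 341. GAGAGA had rank 2 by p there and was in 22.8% of that background (odds ratio 2.34, adjusted exact p = 2.22e-33). The GC-rich words fell there too, CGTCTC from an odds ratio of 3.66 to 2.27 and GCGCAC from 4.32 to 2.96, while AGATAA, chosen after its value was seen, had 2.68 (19.4% against 8.22%). TAATTA was below all other pooled intervals (6.41% against 8.28%, adjusted exact p = 0.0233) and above the GC-matched ones (4.37%, adjusted p = 0.0136).

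The replicates shared somewhat more top peaks than either held alone. Of the 1358 top peaks of replicate 1, 743 (54.7%, interval 52.1 to 57.3%) overlapped a top peak of replicate 2, against 0.404% after relocation (one-sided permutation p = 0.000999, the smallest possible). Of the IDR peaks, 1337 overlapped an interval in both relaxed lists and 720 a top peak in both, while 71 overlapped a top peak of neither. An IDR peak was thus not always ranked alike in the 2 replicates. Signals were close at rpl-35 (71.0 and 67.6 in replicates 1 and 2) and eif-3.C (46.3 and 45.3), whereas epn-1 had 72.6 and 23 and cdc-48.1 45.1 and 89.

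Signal ranks agreed weakly across peaks. Over the 1337 peaks Pearson's r of log2 signal was 0.21 and Spearman's rho 0.23, each with permutation p = 1e-05, the smallest that 100000 permutations can give. Peaks are not independent replicates, and all of them had passed the IDR threshold, which narrows the range of signal. The SD of the log2 ratio of replicate 1 to replicate 2 was 1.00, so the signal of a single peak commonly differed by a factor near 2 between replicates.

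**Figure D5:**
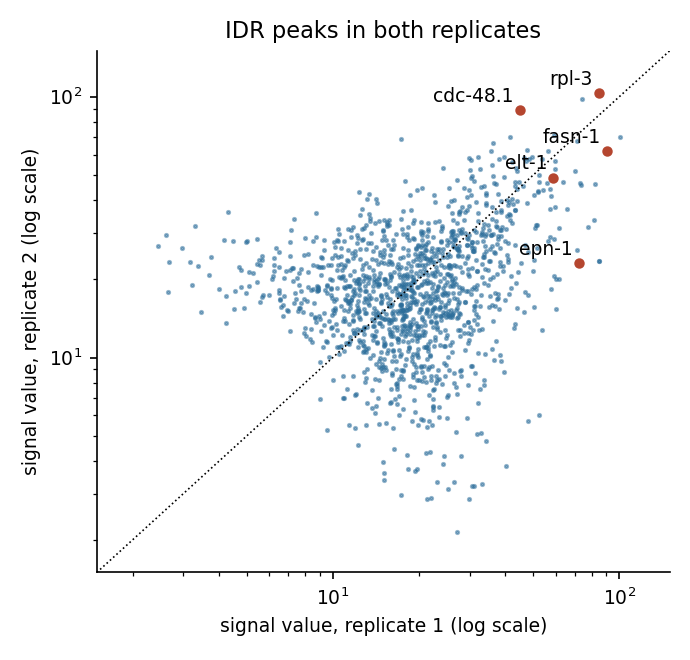
Signal value in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 1337 IDR peaks that overlap an interval in both lists, each point 1 peak. The dotted line marks equal signal, and 5 named peaks are in red, with epn-1 at 72.6 and 23.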

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

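Of the tests in this part, those of X against all pooled intervals and of the length of gaps were chosen only after the result was seen, and the value on genes with a pooled interval, an alternative planned before, was known before its bounds were set. The pooled list holds a signal that the comparisons used only within their background and did not examine on its own: 1140 intervals have the lowest q-value of that list and overlap no IDR peak. In all, 2508 pooled intervals have that q-value. One of them is the interval 8.15 kb from the ceh-16 TSS.

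Ribosomal protein and histone genes carried peaks more often than other genes. GC content does not account for it, since against GC-matched intervals the odds ratio of a summit at these genes was 6.31 (interval 3.54 to 11.6). Nor does a tendency of their promoters to give some interval (odds ratio 12.5 for ribosomal proteins among genes with a pooled interval). Shared reads do not account for the ribosomal protein peaks, where the median and mean share of 31-mers occurring once in the genome were 100%. In histone peaks the median was also 100%, but the mean was 88.0%, against 98.8% for all IDR peaks. Shared reads may thus contribute at some histone genes. Recovery of open or highly transcribed promoters without the tagged protein may still contribute. The homeodomain core was in 5.13% of these 39 peaks (interval 1.42 to 16.9%) and 15.7% of the others. This cannot decide the question, as the core in all IDR windows did not pass against shuffles (15.4% against 14.5%, one-sided permutation p = 0.109). No untagged or other-factor library was analysed here, so the question stays open. No biological explanation was tested.

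The lists left a stretch around ceh-16 without any interval. Ordinary spacing does not readily account for it, as 0.242% of gaps in the pooled list are at least as long, nor does repeated sequence, as 96.7% of the 31-mers in the stretch occur once in the genome. Such gaps do occur elsewhere in the pooled list, away from ceh-16: of the 70 as long, which hold 3.08% of protein-coding genes, 12 others also have over 90% unique 31-mers. With all 4 lists together 9 gaps are as long, and the other 8 have at most 41.4% unique 31-mers. A candidate explanation is that this sequence is carried by the inserted transgene, so that extra copies in a control from the same strain cancel the enrichment or the region was removed. At unc-119, the other gene named in the strain description, the gap was ordinary, with 28.8% of gaps at least as long. The labels do not say that the insertion carries C. elegans unc-119, so the bound set for that test rests on an unstated assumption and the explanation stays open. The absence of a ceh-16 peak is therefore no measure of binding at its own gene.

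The X chromosome held more IDR peaks than its length predicts. Where intervals fall in general does not account for it (odds ratio 1.44 against other pooled intervals, interval 1.26 to 1.63), nor does GC content (1.36 against GC-matched intervals, interval 1.18 to 1.58), nor gene density, since X holds 13.7% of protein-coding genes. Larvae of mixed sex can have 1 or 2 X copies, and an effect of X copy number was not tested. As a hypothesis, the tagged protein may be recovered more often on X. Other explanations, such as more open chromatin on X in these larvae, were not tested.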

How the results depend on the processing

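The promoter excess (54.7 to 58.4% at 1000 bp, left-out replicates included) kept its direction and its side of the threshold under every alternative run. So did the overlap of top peaks (48.4 to 55.2%), the signal correlation (0.19 to 0.23) and the X excess (25.4 to 25.9%). The number of IDR peaks, which was not tested, was 1358 on ce11 and 1397 on ce10. The core share crossed its threshold with 50 bp windows (7.07%), TAATTA alone (6.41%) and the IDR peaks of higher signal (17.5%), ranged from 14.8 to 17.8% with 1 replicate left out, and turned around against the windows 500 bp to each side (23.1%). The number of 6-mers more frequent at summits fell to 341 with the GC-matched background, which was chosen after seeing the data. The log2 difference between promoter and other peaks changed sign without passing its test, at -0.027 to -0.0037 with 1 replicate left out, -0.036 for the top pooled intervals, -0.025 at 500 bp and -0.0028 at 2000 bp. Odds ratios of lists that were never called crossed 1. With 1 replicate left out, these were muscle (0 to 1.02), neurons (0.989 to 2.20) and Wnt signalling (0.916 to 2.76). In the top pooled intervals they were collagens (0.922) and muscle (0.968), and in the IDR peaks of higher signal collagens (0.944) and muscle (0). At 500 bp they were neurons (0) and germline (1.003), and at 2000 bp neurons (0.835). With every gene within 1000 bp they were homeobox (0.846), muscle (0.745), neurons (0.773) and germline (1.22), and with genes that have a pooled interval as background collagens (0.794), muscle (0.834) and neurons (0.595). The causes were not tested. Of the 65 named genes with a peak, 61 kept one in the top list of replicate 2, 56 in that of replicate 1, 50 among the IDR peaks of higher signal, 50 with a 500 bp window, 64 in the top pooled intervals and all 65 with a 2000 bp window. Those lost in replicate 2 were ain-1, lin-66, pas-5 and pat-4, and those lost in replicate 1 were ceh-38, dsh-2, his-4, lin-28, lit-1, nos-3, pas-5, rpn-3 and wrt-10. The 500 bp window lost, among others, ceh-13, daf-12, ain-1, alg-1, dlg-1 and cbp-1. Without ribosomal protein and histone genes, the other 4 called lists passed again. No paired analysis was possible because there is 1 group.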

Other observations

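All tests and genes in this part were chosen after the data were seen. Summits also lay at snoRNA and snRNA genes. Of the 1358 IDR summits, 56 (4.12%, interval 3.19 to 5.32%) lay within 200 bp of one of 346 snoRNA genes, against a mean of 2.14 summits after relocation and 0.41% of the other pooled intervals (odds ratio 10.5, adjusted p = 1.11e-31 by Fisher's exact test). Another 16 lay at snRNA genes (odds ratio 11, adjusted exact p = 4.13e-10), among them the SL2 spliced leader genes sls-2.4 (signal 93.6), sls-2.1 (81.5), sls-2.2 (71.8) and sls-2.8 (47.1). tRNA genes had 38 (odds ratio 2.62, adjusted p = 1.61e-06), but 4 of the 679 IDR peaks of higher signal, no longer past the relocation test (adjusted p = 0.448). Pseudogenes had 8 against a mean of 49.2 after relocation. Of the 56 snoRNA and 16 snRNA summits, 27 and 10 were also promoter peaks of protein-coding genes. None of the 56 snoRNA summits was assigned to a ribosomal protein gene, and 28 overlapped top peaks of both replicates. miRNA genes had 3 summits against 1.65 after relocation (permutation, adjusted p = 0.553). Among heterochronic miRNA genes, the nearest IDR summit was 325 bp from lin-4 (signal 24.8), 1863 bp from let-7 (32.4), 2275 bp from mir-241, 4049 bp from mir-48 and 34.1 kb from mir-84.

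Peaks of the called lists were also counted on X and autosomes apart. Among X-linked genes, 5 of 6 heterochronic genes had a peak (puf-9, lin-14, daf-12, ain-1 and alg-1), against 5.93% of all X-linked genes (Fisher's exact, adjusted p = 2.38e-05). On autosomes 2 of 12 had one, lin-28 and lin-66, against 3.14% of all autosomal genes (odds ratio 6.19, interval 0.658 to 29.2, adjusted exact p = 0.079). Nuclear hormone receptor genes had peaks at 8 of 27 on X (odds ratio 6.96, adjusted exact p = 0.000327) and 12 of 247 on autosomes (odds ratio 1.59, adjusted p = 0.148). The seam and epidermal list also passed on X (2 of 3, adjusted exact p = 0.0202) and not on autosomes (2 of 15, odds ratio 4.76, adjusted exact p = 0.105). The other lists passed on autosomes and not on X: Hox genes and cofactors had 0 of 3 on X and 3 of 8 on autosomes (adjusted exact p = 0.00367), histones 2 of 5 (0.0533) and 9 of 53 (0.000143), and ribosomal proteins 1 of 2 (0.138) and 27 of 77 (1.64e-20). The difference between X and autosomes was not tested, and the X lists are small. At any distance, 18 genes were nearest to 4 or more IDR peaks, 4 of them on X. egl-27, an MTA-class chromatin regulator gene, had 7, and ZC190.4 and unc-62 had 5 each. The others had 4 each: the junction gene ajm-1, the spectraplakin gene vab-10, cyd-1, which encodes cyclin D, anc-1, elt-1, fasn-1, ifbp-1, mdl-1, myrf-1, nhr-25, ppfr-1, zfp-1, F57G12.1, W06H8.6 and Y111B2A.12.

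The top peaks that 1 replicate held alone differed between the replicates. Of the 618 in replicate 2 alone, 62.1% were at promoters and 19.3% held the homeodomain core, against 53.0% and 12% of the 615 in replicate 1 alone (Fisher's exact p = 0.00125 and 0.000544). The sets also differed in mean GC, 42.9% in replicate 2 alone and 46.0% in replicate 1 alone, and the core difference was not tested at equal GC. With 2 times as many top peaks the core difference was 1.10 percentage points (exact p = 0.463), while the promoter difference was 6.27 (p = 0.00139). With 1 library on each side, these values compare the libraries and not conditions.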
